A study of Caenorhabditis elegans with 18 samples.

How the data were processed

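Total small RNA was purified from embryos taken before the bean stage, after 60 to 65 h of growth from synchronised first larvae. It was treated with TAP, an enzyme that turns capped and triphosphate RNA ends into monophosphates, to which adapters can be joined. Libraries were sequenced as single-end reads of 50 bases on an Illumina HiSeq. Per the labels, the authors clipped adapters and collapsed reads with the FASTX-Toolkit and mapped them with QuasR to genome release WS220 (ce10), with tool versions not stated. The deposited table holds counts, whole numbers of reads for each 20-bp bin and library, with both strands together. The series text also states scaling to total reads and subsetting by read length, which whole numbers without length classes do not show, so the values were treated as unscaled counts. The table covers chromosome I and chromosome II up to 5.9 Mb, and totals and shares refer to these regions alone.

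The annotation at hand was of another genome build than ce10, and coordinates were not converted, so bins carry no gene names and positions are those of ce10. Gene lists fixed in advance, small RNA classes, read lengths and scaling to microRNA reads were therefore not used here. Rows of one name were not summed, for the same reason.

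All 18 libraries were fitted in one model with a coefficient for each of the 6 groups, in edgeR 4.0.16 under R 4.3.3. Bins were kept by filterByExpr with a minimum count of 10, scaled by TMM, and tested with glmQLFTest at a Benjamini-Hochberg adjusted p of 0.05 within each comparison. Of the bins, 38100 were tested, and 10730 windows of 1 kb on a fixed grid were tested in the same way. Interactions were the double mutant minus both single mutants plus N2. Standard errors are the size of a log2 fold change divided by the square root of its F statistic. The replicate numbers were not used as a block, since the labels do not say that a number marks a shared culture or day. In a later check, libraries with the same number were no more alike than others. The design, the comparisons and the rule for naming were fixed before the data were examined. That rule names the 10 largest rises and 10 largest falls in each comparison with N2 and 3 of each in the other comparisons. Candidates pass the threshold and have a higher group mean above the median of the features tested. In comparisons of 2 groups, but not in interactions, all 3 libraries of a group also lie on one side of the other 3. The rule was applied to windows with its condition on gene names left out, a choice made after the table was seen. The examples printed are a part of the 82 windows it named, 136 when counted once per comparison. A window with 3 reads or fewer over the libraries of a group is given no fold change against it.

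Shares of reads were compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment. Overlaps of calls were tested by one-sided Fisher's exact tests among the features tested. Data were simulated with the design of the study, with changes placed in nrde-3 alone and in bins of higher expected counts. In nrde-3 against N2, tests on bins recovered 26.0% of 2-fold and 94.0% of 4-fold rises, and 18.0% and 84.0% of falls of the same size, 50 bins each. With reads of met-2;nrde-3 replicates 1 and 2 duplicated in the simulation, the tests recovered 20.0% and 88.0% of rises and 16% and 70.0% of falls. Unchanged bins made up 5.93% of the calls without duplication and 2.02% with it. Recovery of changes in met-2;nrde-3 or in bins of few reads was not simulated. Alternatives were RLE factors, library totals, DESeq2 1.42.0, no filter, a 10 times stricter filter, only the groups compared, a replicate block and each library left out in turn. Added after seeing the data were voom with sample quality weights (limma 3.58.1), 1-kb windows, omission of the right end of chromosome I and omission of met-2;nrde-3 replicates 1 and 2. Tables were handled with the R package data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.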

Results

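Small RNA was sequenced from early Caenorhabditis elegans embryos of 6 strains, with 3 libraries of each. The strains were wild type N2 and worms lacking nrde-3, met-2 or set-25, or lacking nrde-3 together with met-2 or with set-25. NRDE-3 is an Argonaute protein that carries small RNAs into nuclei of somatic cells, and MET-2 and SET-25 are histone methyltransferases that act on lysine 9 of histone H3. Groups carry the names given by the labels, and the genotypes were not checked, since the 3 mutated genes lie on chromosomes outside the regions covered. Values are reads in 20-bp bins of genome build ce10, summed over both strands and all read lengths, on chromosome I and on chromosome II up to 5.9 Mb. Total reads in these regions were 2829783, 4384593 and 4147419 for N2, 2115436, 3695174 and 2611531 for nrde-3 and 4207472, 3618255 and 4073725 for met-2. They were 3644082, 4022919 and 3732718 for set-25, 1680028, 2694426 and 2539942 for met-2;nrde-3 and 4027213, 3999457 and 3515896 for set-25;nrde-3. The growth protocol names 2 biological replicates while 3 libraries are numbered per strain, so p-values measure the spread between these libraries. Windows are 1 kb long, their levels are normalised read counts (CPM with TMM factors, mean ± SD, n = 3), and changes are log2 fold changes ± SE from edgeR with its adjusted p. Each window named in a comparison of 2 groups had the 3 libraries of the first group all on one side of the 3 of the other. For windows named in the interactions this was not required.

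The last 13 kb of chromosome I, the end of the chromosome that holds the ribosomal RNA gene array, took a large share of the reads. That share was 27.0% ± 5.15 in N2 (SD, n = 3), 44.5% ± 10.9 in nrde-3, 48.5% ± 4.39 in met-2 and 57.5% ± 4.09 in set-25. It was 61.3% ± 6.56 in set-25;nrde-3 and 33.6% ± 10.9 in met-2;nrde-3. All 3 libraries of nrde-3, met-2, set-25 and set-25;nrde-3 lay above all 3 of N2 (exact two-sided permutation p = 0.1 in each, the smallest that 3 against 3 allows, adjusted p = 0.136 over 15 comparisons). For met-2;nrde-3 the exact permutation p was 0.4 (adjusted p = 0.429). The covered part of chromosome II held 26.8% ± 2.27 of reads in N2, 17.4% ± 3.72 in nrde-3, 13.8% ± 1.30 in met-2 and 14.1% ± 1.44 in set-25. It held 23.1% ± 4.18 in met-2;nrde-3 and 11.9% ± 1.95 in set-25;nrde-3. Bins with at least 1 read made up 5.76% and 7.19% of all bins in met-2;nrde-3 replicates 1 and 2, and 11.3% to 17.9% in the 16 other libraries.

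**Figure D1:**
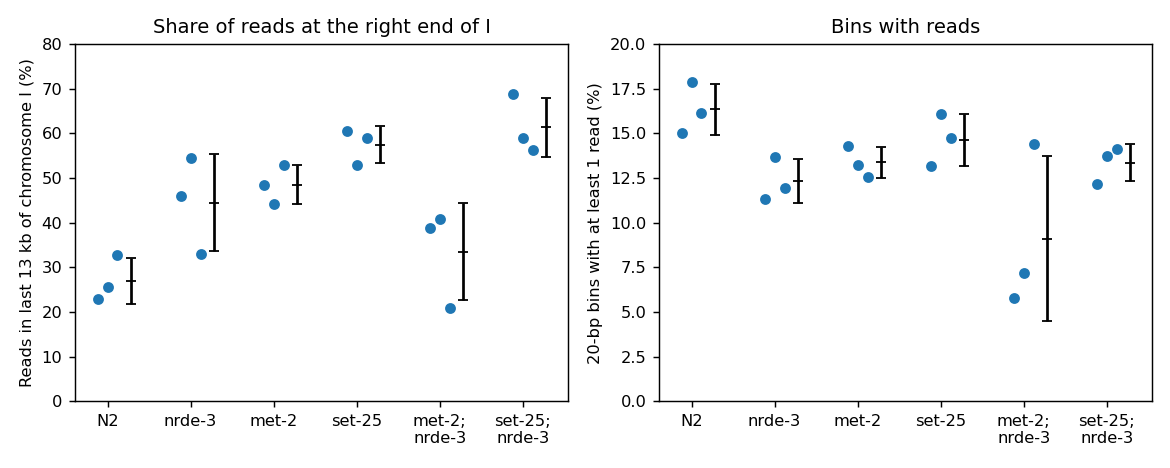
Share of each library's reads in the last 13 kb of chromosome I (left, percent) and share of 20-bp bins with at least 1 read (right, percent), by strain. Points are libraries and bars show the mean ± SD of 3. N2 had the lowest mean share at the chromosome end, 27.0%, and met-2;nrde-3 replicates 1 and 2 had the fewest bins with reads.

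The comparison of nrde-3 with N2 asked which small RNAs depend on NRDE-3. On chromosome II, which held 10026 of 38100 bins tested, lay 405 of 645 falling bins, while 133 of 281 rising bins lay at the right end of chromosome I. The window at II: 311017-312016 dropped from 818 ± 107 to 84.4 ± 50.9, a change of -3.28 ± 0.26 (adjusted p = 4.97e-10). The window at II: 2996017-2997016 changed by -3.58 ± 0.25 (adjusted p = 5.71e-11), and those at I: 10913020-10914019 and II: 2137017-2138016 changed by -3.16 ± 0.17 and -2.95 ± 0.16. At I: 9170001-9171000 the level rose from 85.7 ± 3.83 to 417 ± 27.6, a change of 2.28 ± 0.11 (adjusted p = 1.83e-13). Windows at II: 63017-64016 and I: 13464020-13465019 rose by 2.29 ± 0.31 and 1.93 ± 0.21. Of 38100 bins tested with edgeR, 281 were higher and 645 lower in nrde-3, while windows were called 241 higher and 181 lower. Of these windows, 74 and 99 changed at least 2-fold. With the right end of chromosome I left out, 179 bins were higher and 652 lower. Scaling by library totals alone gave 103 higher and 739 lower bins, with the median of all bins moved by -0.25. With N2 replicates 1, 2 and 3 and nrde-3 replicates 1 and 2 left out in turn, higher bins numbered 55, 79, 162, 128 and 85 and lower bins numbered 497, 514, 534, 497 and 473.

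The comparison of set-25 with N2 asked which small RNAs depend on that methyltransferase. Of 485 rising bins, 351 lay at the right end of chromosome I, where 11 of 13 windows rose. There, I: 15067020-15068019 rose from 29804 ± 7966 to 105353 ± 16961, a change of 1.82 ± 0.32 (adjusted p = 4.07e-04). Away from that end, the window at I: 5271001-5272000 rose from 121 ± 4.65 to 597 ± 16.8, a change of 2.30 ± 0.13 (adjusted p = 3.18e-12). Adjoining windows at I: 12506020-12507019 and I: 12507020-12508019 fell, with changes of -3.08 ± 0.22 and -3.01 ± 0.26 (adjusted p = 2.61e-10 and 4.54e-09). Another run at I from 6820001 to 6823000 fell as well, with changes of -2.54 ± 0.25, -2.96 ± 0.17 and -2.05 ± 0.24 in its 3 windows. The model called 485 higher and 412 lower bins, and 115 and 386 when the right end was left out of bins and totals, and windows were called 221 higher and 224 lower. Library totals alone gave 346 higher and 2019 lower bins, with the median of all bins moved by -0.60. With N2 replicates 1, 2 and 3 and set-25 replicates 1, 2 and 3 left out in turn, higher bins numbered 325, 325, 412, 366, 416 and 385 and lower bins numbered 182, 199, 260, 176, 212 and 208.

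The comparison of set-25;nrde-3 with N2 asked for the joint effect of both losses. The window at II: 311017-312016 fell to 35.5 ± 3.88, a change of -4.53 ± 0.28 (adjusted p = 2.07e-12), and that at II: 2996017-2997016 changed by -4.32 ± 0.27 (adjusted p = 2.07e-12). The abundant window at II: 2136017-2137016 dropped from 2139 ± 208 to 224 ± 31.1, a change of -3.26 ± 0.18. Windows at I: 14679020-14680019, I: 11495020-11496019 and II: 2269017-2270016 rose by 4.73 ± 0.28, 4.19 ± 0.27 and 3.91 ± 0.26. Adjoining windows at I: 10630020-10631019 and I: 10631020-10632019 rose by 3.58 ± 0.27 and 3.31 ± 0.15 over N2, and by 3.02 ± 0.27 and 2.90 ± 0.15 over set-25. Against N2, 842 bins were higher and 1068 lower, while windows were called 604 higher and 389 lower. At the right end of chromosome I lay 372 of the higher bins, and 497 higher and 1012 lower bins were called with that end left out. Scaling by totals alone gave 419 higher and 4069 lower bins, with the median of all bins moved by -0.71.

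Setting set-25;nrde-3 against set-25 asked for the effect of losing nrde-3 where set-25 was already lost, with no library in common with nrde-3 against N2. Among bins 77 were higher and 453 lower, and 274 of the lower bins lay on chromosome II. The balance was the other way among 1-kb windows, which were called 405 higher and 205 lower, and 77 and 108 of these changed at least 2-fold. The window at II: 311017-312016 changed by -3.15 ± 0.27 (adjusted p = 8.81e-09) and that at II: 2996017-2997016 by -3.11 ± 0.27 (adjusted p = 8.81e-09). Of 645 bins lower in nrde-3 than in N2, 347 were among those lower in set-25;nrde-3 than in set-25, where 7.67 would be shared by chance. Among 1-kb windows the shared falls numbered 72, with 3.46 by chance (one-sided Fisher's exact p = 1.54e-79, adjusted p = 6.16e-79 over 48 overlap tests). Of the windows and bins lower in nrde-3, 14 and 2 were higher here, and chance counts for these were not computed. Shared rising bins numbered 13, with 0.568 by chance (one-sided Fisher's exact p = 1.74e-14, adjusted p = 2.70e-14). Neighbouring bins are not independent, so these p-values are smaller than independent loci would give. With set-25 replicates 1, 2 and 3 and set-25;nrde-3 replicates 2 and 3 left out in turn, higher bins numbered 24, 18, 27, 33 and 31 and lower bins numbered 343, 294, 363, 264 and 280.

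Setting set-25;nrde-3 against nrde-3 asked for the effect of losing set-25 where nrde-3 was already lost. A rise of 4.64 ± 0.30 was measured at I: 14679020-14680019 (adjusted p = 8.81e-12). At I: 8386001-8387000 the level fell from 70.6 ± 2.20 to 5.38 ± 0.757, a change of -3.70 ± 0.27 (adjusted p = 8.69e-11). Bins higher and lower numbered 427 and 321, and windows were called 404 higher and 341 lower. With library totals as the scale, the split was 153 higher and 1203 lower bins, with the median of all bins moved by -0.47. With nrde-3 replicates 1 and 3 and set-25;nrde-3 replicates 1, 2 and 3 left out in turn, higher bins numbered 180, 169, 277, 221 and 249 and lower bins numbered 167, 131, 221, 149 and 138. Without nrde-3 replicate 2 there were 529 higher and 288 lower bins. The test of whether the nrde-3 effect differed between set-25 and wild-type backgrounds called 17 bins above 0 and 11 below 0. At adjoining windows I: 7894001-7895000 and I: 7895001-7896000, levels were 50.4 ± 5.17 and 33.0 ± 1.20 in N2 and 7.72 ± 1.87 and 3.22 ± 1.14 in nrde-3. In set-25;nrde-3 they were 55.3 ± 9.81 and 34.0 ± 4.54, with interactions of 2.92 ± 0.27 and 3.44 ± 0.35 (adjusted p = 8.35e-08 and 3.84e-07). For this interaction, library totals alone gave 12 bins above and 4 below 0. With N2 replicates 1, 2 and 3, set-25 replicates 1, 2 and 3, nrde-3 replicate 1 and set-25;nrde-3 replicates 1, 2 and 3 left out in turn, bins above 0 numbered 12, 12, 14, 11, 12, 12, 10, 15, 12 and 10 and bins below 0 numbered 1, 4, 6, 5, 5, 6, 4, 7, 6 and 3.

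Libraries labelled met-2 differed from N2 over more of the covered genome than any other single or double mutant, with 14118 of 38100 bins called. Reads fell most on the left part of chromosome II, where 267 of 545 windows between 1 and 2 Mb fell and the median change was -1.03. The median was -0.29 between 14 and 15 Mb of chromosome I, against 0.27 between 5 and 6 Mb in its centre. All 13 windows at the right end of chromosome I rose. A run of 3 windows at I from 7135001 to 7138000 rose from 1.81 ± 0.905, 2.40 ± 0.679 and 3.89 ± 0.788 to 1103 ± 41.9, 1106 ± 19.7 and 1162 ± 38.3. Their changes were 9.25 ± 0.27, 8.83 ± 0.31 and 8.19 ± 0.23 (adjusted p = 1.05e-20, 4.60e-19 and 8.83e-21). A further window, I: 11968020-11969019, rose by 6.62 ± 0.23. At I: 842001-843000 the level fell from 78.8 ± 3.13 to 0.441 ± 0.529, a change of -7.31 ± 0.28 (adjusted p = 4.15e-18). Windows at I: 1069001-1070000 and I: 1549001-1550000 changed by -5.61 ± 0.20 and -5.63 ± 0.16, and the window at II: 311017-312016, lower in nrde-3 too, by -5.50 ± 0.29. The called bins were 5614 higher and 8504 lower, and the called windows 1642 higher and 2471 lower. Under library totals alone there were 3404 higher and 11451 lower bins, with the median of all bins moved by -0.56.

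**Figure D2:**
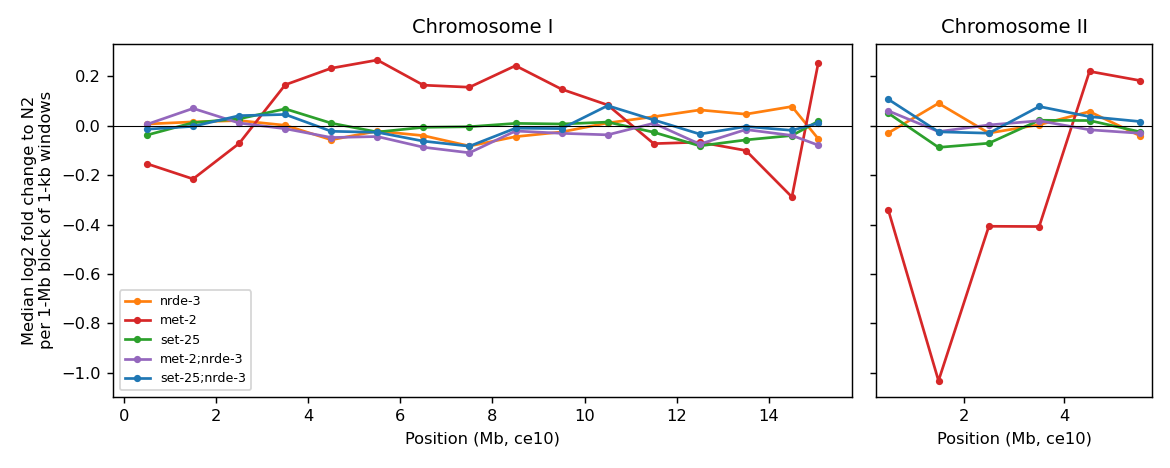
Median log2 fold change to N2 of the 1-kb windows in each 1-Mb block, by position on chromosome I and on the covered part of chromosome II, with 1 line per mutant. Medians for met-2 ran from -1.03 to 0.27, and those of the other 4 mutants from -0.11 to 0.11.

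Libraries labelled met-2;nrde-3 had a median Spearman correlation with N2 of 0.880 across windows (range 0.847 to 0.944). For met-2 it was 0.788 (0.779 to 0.794). The met-2;nrde-3 libraries correlated with each other at only 0.815 to 0.889, and the N2 libraries at 0.954 to 0.964. Windows are not independent replicates. The window at I: 14855020-14856019 rose from 0.143 ± 0.131 in N2 to 129 ± 29.0, from 2 to 1164 reads over 3 libraries each (adjusted p = 9.73e-15), and held 1.11 ± 0.763 in nrde-3, 0.381 ± 0.431 in met-2, 0.203 ± 0.181 in set-25 and 0.342 ± 0.313 in set-25;nrde-3. Windows at I: 14679020-14680019, II: 2269017-2270016 and I: 11495020-11496019 rose by 4.48 ± 0.28, 4.11 ± 0.26 and 3.91 ± 0.27. Falls included I: 12506020-12507019 and I: 6821001-6822000, with changes of -2.64 ± 0.22 and -2.27 ± 0.17. The bins called were 114 higher and 367 lower and the windows 282 higher and 218 lower, and with N2 and met-2;nrde-3 alone in the fit the count was 15. Library totals alone gave 77 higher and 108 lower bins. With N2 replicates 1, 2 and 3 and met-2;nrde-3 replicates 2 and 3 left out in turn, higher bins numbered 29, 35, 37, 68 and 494 and lower bins numbered 228, 182, 253, 217 and 5604.

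Setting met-2;nrde-3 against met-2 asked for the effect of losing nrde-3 where met-2 was already lost. At I: 842001-843000 the change was 7.23 ± 0.29 (adjusted p = 7.88e-18), and the window at I: 7135001-7136000 changed by -9.11 ± 0.28 (adjusted p = 3.39e-20). Higher bins numbered 8207 and lower bins 7224, and windows were called 2584 higher and 2018 lower. Of the 645 bins lower in nrde-3 than in N2, 39 were lower here, with 122 by chance (one-sided Fisher's exact p = 1.00, adjusted p = 1.00), and 496 were higher. Of the 281 bins higher in nrde-3, 85 were higher here, with 60.5 by chance (one-sided Fisher's exact p = 3.84e-04, adjusted p = 4.72e-04), and 154 were lower. The balance was the other way among 1-kb windows, where 136 of 241 were higher here, with 58 by chance (one-sided Fisher's exact p = 1.48e-27, adjusted p = 2.97e-27), and 49 were lower. Among windows changed at least 2-fold, 21 of 74 were higher here, with 14.98 by chance, and 13 were lower. That smaller overlap did not pass the threshold (one-sided Fisher's exact p = 0.0586, adjusted p = 0.0686). Of the 181 windows lower in nrde-3, 28 were lower here, with 34.0 by chance, and 132 were higher. Scaling by totals alone gave 11551 higher and 3773 lower bins, with the median of all bins moved by 0.65. With met-2;nrde-3 replicate 3 left out, higher bins numbered 7394 and lower bins numbered 10800.

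Setting met-2;nrde-3 against nrde-3 asked for the effect of losing met-2 where nrde-3 was already lost. The window at I: 304001-305000, lower in nrde-3 than in N2, rose from 2.12 ± 0.823 to 29.3 ± 6.99, a change of 3.79 ± 0.38 (adjusted p = 4.24e-08). Adjoining windows at II: 2005017-2006016 and II: 2006017-2007016 changed by -4.61 ± 0.63 and -4.39 ± 0.45 (adjusted p = 6.96e-06 and 5.91e-08). Higher bins numbered 599 and lower bins 961, and windows were called 432 higher and 444 lower. With library totals as the scale, the split was 901 higher and 367 lower bins, with the median of all bins moved by 0.33. With nrde-3 replicates 1 and 2 and met-2;nrde-3 replicate 3 left out in turn, higher bins numbered 306, 322 and 833 and lower bins numbered 818, 543 and 5137. The test of whether the nrde-3 effect differed between met-2 and wild-type backgrounds called 6119 bins above 0 and 4251 below 0. Its largest values among named windows included 9.22 ± 0.38 at I: 7894001-7895000, 8.22 ± 0.38 at II: 2996017-2997016 and -9.29 ± 0.80 at I: 7135001-7136000 (adjusted p = 5.41e-17, 4.72e-16 and 2.34e-10). For this interaction, library totals alone gave 9773 bins above and 1809 below 0, with the median of all bins moved by 0.89. With met-2;nrde-3 replicate 3 left out, bins above 0 numbered 5697 and bins below 0 numbered 7286.

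**Figure D3:**
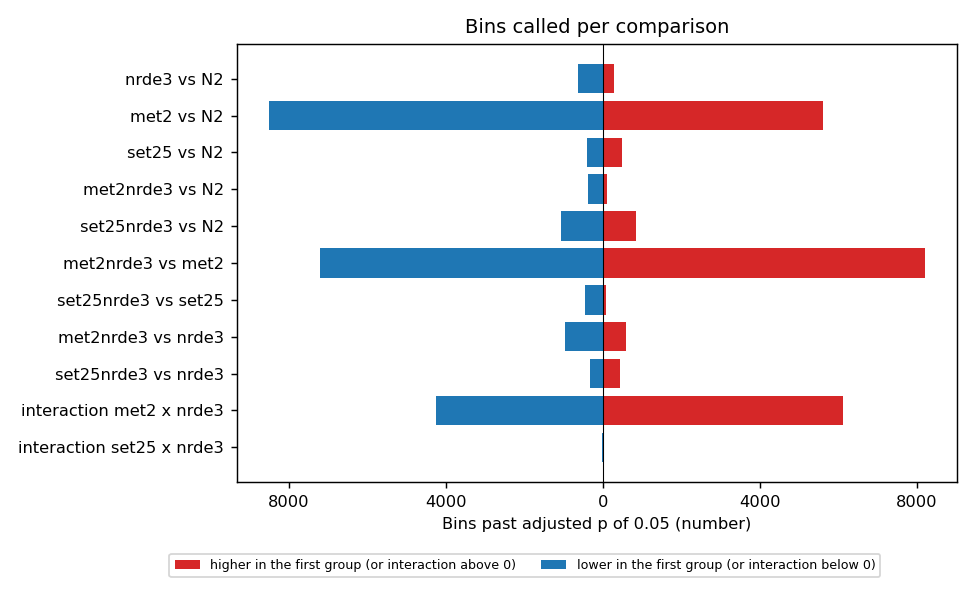
Number of 20-bp bins past the adjusted p threshold of 0.05 in each comparison, with bins higher in the first-named group to the right of 0 and lower ones to the left. Comparisons with met-2 on 1 side called 14118 and 15431 bins, and the set-25 interaction called 28.

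Bins that fell when nrde-3 was lost from set-25 worms were followed in the groups outside that comparison. All 18 libraries still shared the filter, the scaling and the estimates of spread behind the choice. Over these 453 bins the mean log2 level relative to N2 was -1.94 ± 0.41 in nrde-3, -2.47 ± 0.03 in met-2 and -0.67 ± 0.21 in met-2;nrde-3 (SD, n = 3). The met-2;nrde-3 replicates stood at -0.54, -0.91 and -0.56, while the mean over all other bins was -0.52, -0.35 and -0.02 in the same libraries, so in replicate 1 these bins lay no lower than the rest by more than the N2 spread. In met-2 the other bins were at -0.11, -0.13 and -0.17. The N2 libraries themselves had an SD of 0.09. Each of 6 group differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, and an adjusted p of 0.1. Many of the 453 bins lay close together. On chromosome II, 102 of them lay in 17 windows between 2 and 3 Mb, and 96 in 18 windows between 3 and 4 Mb. Bins of one window are not independent loci. In edgeR, 347 of the 453 bins were lower in nrde-3 than in N2, 402 in met-2 and 62 in met-2;nrde-3. Between met-2;nrde-3 and met-2, 371 were higher and 30 lower. These groups were compared after the data had been seen.

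**Figure D4:**
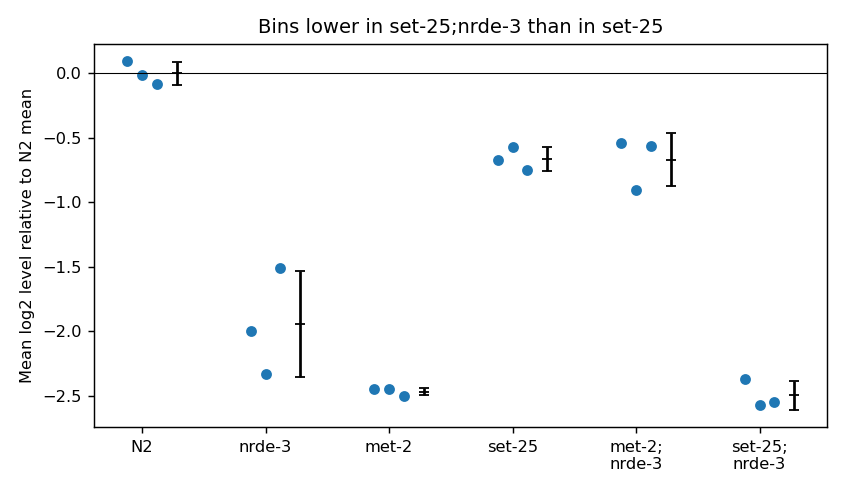
Mean log2 level relative to the N2 mean over the 453 bins lower in set-25;nrde-3 than in set-25, by strain. Points are libraries and bars show the mean ± SD of 3. The bins were chosen by the comparison of both set-25 groups, and met-2 (-2.47) lies below nrde-3 (-1.94) and met-2;nrde-3 (-0.67).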

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

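The tests of exchanged labels, of a need for met-2, of deleted sequence and of low complexity were chosen only after the result was seen, and the others were fixed before. Interaction tests asked whether the effect of nrde-3 loss differed from that in the wild-type background. They called 10370 bins for met-2 and 28 bins for set-25, with libraries taken as labelled. An exchange of the met-2 and met-2;nrde-3 labels stays open below, as does chance for both interactions.

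Libraries labelled met-2 changed at many bins and libraries labelled met-2;nrde-3 at few. Depth is argued against for the many bins in met-2. With all libraries thinned to 1026993 reads outside the right end of chromosome I, met-2 against N2 still called 9435 bins. After the same thinning, nrde-3 called 748 and met-2;nrde-3 314. Thinning equalised reads but not the share of bins with reads, which was 5.76% and 7.19% in the sparsest met-2;nrde-3 libraries. Thinning alone therefore cannot tell whether that low share kept the calls few in met-2;nrde-3. The same met-2;nrde-3 libraries called 15431 bins against met-2, which argues against a general loss of calls from that share. Whether smaller changes were missed was not tested. A candidate explanation is that labels of the met-2 and met-2;nrde-3 groups were exchanged. Over the bins lower in set-25;nrde-3 than in set-25, met-2;nrde-3 lay 1.80 (log2) above met-2. There, met-2 (-2.47 relative to N2) lay below nrde-3 (-1.94). Rises gave contrary values. Over the 405 windows higher in set-25;nrde-3 than in set-25, met-2;nrde-3 (0.17) lay near nrde-3 (0.20). It lay 0.41 above met-2 (-0.24), as the labels have it. All other windows stood at -0.15 in met-2;nrde-3, -0.05 in nrde-3 and -0.22 in met-2, so met-2 lay near its own background at the 405 windows. Over the 77 higher bins the levels were 0.14 in met-2;nrde-3 and 0.55 in met-2, a difference of -0.40. All other bins stood at -0.30 and -0.16 in these 2 groups. A biological explanation is that the falling reads need met-2 and return when nrde-3 is lost as well. It predicts a positive interaction (median 4.02 over the bins lower in set-25;nrde-3 than in set-25). It cannot be told apart from an exchange by these values, because neither locus was covered.

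A larger share of windows fell on the left part of chromosome II than elsewhere in libraries labelled met-2. Deleted or unmappable sequence is argued against between 1 and 2 Mb, since the 267 windows that fell there kept a median of 17.3% of the N2 level and 0 had no reads. The effect of the met-2 mutation itself stays open and was not tested apart from the labels.

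With met-2;nrde-3 replicate 3 left out, 6098 bins were called against N2 in place of 481. The low complexity of replicates 1 and 2 is a candidate explanation, and it predicts that they lost bins independently of each other. Over 23595 tested bins with at least 10 reads in replicate 3, chosen without any call, 15.6% were empty in replicate 1 and 9.13% in replicate 2, against 0.0720% to 7.01% in the 15 libraries of other groups. Bins empty in both numbered 786, which was 1.36 times the 578 that independent loss gives at the same replicate 3 counts, so the excess of shared bins stays open. No biological explanation was tested.

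The 10 splits of the 6 libraries of a pair of groups are too few for a share under 0.05. The real split was the only 1 of 10 to call as many bins in each of the 9 comparisons of 2 groups. All other splits mixed libraries of both groups, which adds any group difference to the spread within groups. Their low counts are therefore no chance value. The highest other split called 0 bins for nrde-3 against N2 (real 926), met-2 against N2 (real 14118), set-25 against N2 (real 897), met-2;nrde-3 against N2 (real 481), set-25;nrde-3 against N2 (real 1910) and set-25;nrde-3 against set-25 (real 530). It called 1 for met-2;nrde-3 against met-2 (real 15431), 137 for met-2;nrde-3 against nrde-3 (real 1560) and 3 for set-25;nrde-3 against nrde-3 (real 748). For the met-2 interaction, 1 of 100 drawn splits, the real one, called as many as 10370 bins. The 14 other splits that kept met-2 and met-2;nrde-3 libraries apart called 8677 to 10043, and the 85 that mixed them at most 145. The count therefore came mostly from the difference between these 2 groups, and little from which libraries were N2 and which nrde-3. For the set-25 interaction, 7 of 100 splits called at least 28 bins and the highest other 1252. All the others among these 7 kept N2 and nrde-3 libraries apart, or set-25 and set-25;nrde-3 libraries, or both as in the highest, where 1 pair was reversed and the nrde-3 effects of both backgrounds were added. The 75 that mixed both pairs called 0. The structure behind the counts of several times the real one was thus group differences left intact, so these splits gave no chance value for either interaction, and whether chance can be excluded stays open for both.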

How the results depend on the processing

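Voom with quality weights, 1-kb windows and the omissions of the right end and of both low-complexity libraries were chosen after seeing the data. Scaling to microRNAs, sums over rows of one name, other pseudocounts and gene list tests were not run, since bins have no names and the values are counts. Of the alternative counts of called bins and overlaps, 127 were within 1.5 times the main count and 69 were not, and no named window turned in direction. Named windows kept their call in 2095 of their alternatives and lost it in 13. Depth limits calls at bins with few reads. The cause of a moved count was not tested, except that a stricter filter and windows test fewer features.

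Called bins were, with library totals, 2365 for set-25 against N2, 185 for met-2;nrde-3 against N2, 4488 for set-25;nrde-3 against N2, 1356 for set-25;nrde-3 against nrde-3 and 16 for the set-25 interaction, with DESeq2 102 for the set-25 interaction and with no filter 18 for the set-25 interaction. With a 10 times stricter filter they were 3542 for met-2 against N2, 317 for met-2;nrde-3 against N2, 3497 for met-2;nrde-3 against met-2, 963 for met-2;nrde-3 against nrde-3 and 3149 for the met-2 interaction. With only the groups compared in the fit they were 1437 for nrde-3 against N2, 1978 for set-25 against N2, 15 for met-2;nrde-3 against N2, 3217 for set-25;nrde-3 against N2, 9128 for met-2;nrde-3 against met-2, 1065 for set-25;nrde-3 against set-25, 330 for met-2;nrde-3 against nrde-3 and 117 for the set-25 interaction. With voom they were 1666 for nrde-3 against N2, 2000 for set-25 against N2, 92 for met-2;nrde-3 against N2, 3487 for set-25;nrde-3 against N2, 1297 for set-25;nrde-3 against set-25, 737 for met-2;nrde-3 against nrde-3, 1440 for set-25;nrde-3 against nrde-3 and 145 for the set-25 interaction. Called 1-kb windows were 422 for nrde-3 against N2, 4113 for met-2 against N2, 445 for set-25 against N2, 993 for set-25;nrde-3 against N2, 4602 for met-2;nrde-3 against met-2, 876 for met-2;nrde-3 against nrde-3, 3238 for the met-2 interaction and 143 for the set-25 interaction. Without the right end of chromosome I the count was 501 for set-25 against N2, and without both low-complexity libraries 67 for met-2;nrde-3 against N2 and 1011 for met-2;nrde-3 against nrde-3.

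With 1 library left out in turn, called bins ran from 552 to 964 for nrde-3 against N2, 12323 to 12719 for met-2 against N2, 507 to 672 for set-25 against N2, 217 to 6098 for met-2;nrde-3 against N2, 1356 to 1545 for set-25;nrde-3 against N2, 13765 to 18194 for met-2;nrde-3 against met-2, 297 to 445 for set-25;nrde-3 against set-25, 865 to 5970 for met-2;nrde-3 against nrde-3, 300 to 817 for set-25;nrde-3 against nrde-3, 9186 to 12983 for the met-2 interaction and 13 to 27 for the set-25 interaction. Omission of these replicates moved a count by over 1.5 times, with the counts left in brackets. For nrde-3 against N2 these were N2 1 and 2 (552, 593) and nrde-3 2 (558). For set-25 against N2 these were N2 1 and 2 (507, 524) and set-25 1 and 3 (542, 593). For met-2;nrde-3 against N2 these were N2 1, 2 and 3 (257, 217, 290) and met-2;nrde-3 2 and 3 (285, 6098). For set-25;nrde-3 against set-25 these were set-25 2 (312) and set-25;nrde-3 2 and 3 (297, 311). For met-2;nrde-3 against nrde-3 these were nrde-3 2 (865) and met-2;nrde-3 3 (5970). For set-25;nrde-3 against nrde-3 these were nrde-3 1 and 3 (347, 300) and set-25;nrde-3 1, 2 and 3 (498, 370, 387). For the set-25 interaction these were N2 1 and 2 (13, 16), set-25 1, 2 and 3 (16, 17, 18), nrde-3 1 (14) and set-25;nrde-3 2 and 3 (18, 13).

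With the replicate number as a block, called bins were 811 for nrde-3 against N2, 13654 for met-2 against N2, 822 for set-25 against N2, 364 for met-2;nrde-3 against N2, 1786 for set-25;nrde-3 against N2, 14824 for met-2;nrde-3 against met-2, 483 for set-25;nrde-3 against set-25, 1381 for met-2;nrde-3 against nrde-3, 652 for set-25;nrde-3 against nrde-3, 9776 for the met-2 interaction and 23 for the set-25 interaction, each within 1.5 times the count without the block. The pairing of libraries by number was not seen in the residuals, where correlations of libraries of one number ran from -0.0673 to 0.0688.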

Other observations

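These overlaps were chosen only after the data were seen. At some named windows the 4 strains with a methyltransferase mutation held more reads than N2 and nrde-3. The window at I: 14679020-14680019 held 1.17 ± 0.140 CPM in N2 and 1.16 ± 0.614 in nrde-3 (SD, n = 3). It held 12.6 ± 0.926 in met-2, 16 ± 0.321 in set-25, 26.8 ± 4.94 in met-2;nrde-3 and 31.9 ± 1.64 in set-25;nrde-3. At I: 11495020-11496019 the 4 methyltransferase mutants held 20.5, 25.7, 36.3 and 43.7, against 2.24 in N2 and 2.6 in nrde-3. For the pair of set-25 against N2 and set-25;nrde-3 against nrde-3, which share no library, 106 windows rose and 102 fell in both, with 8.32 and 7.12 by chance (one-sided Fisher's exact adjusted p = 1.64e-93 and 3.74e-95). Of windows that rose and fell in the first, 6 and 4 went the opposite way in the second. Among bins, 105 rose and 115 fell in both, with 5.44 and 3.47 by chance (exact adjusted p = 2.87e-103 and 2.81e-144), and 2 and 2 went opposite ways. For set-25 against N2 paired with met-2;nrde-3 against nrde-3, which share no library, 82 windows rose and 100 fell in both, with 8.90 and 9.27 by chance (one-sided Fisher's exact adjusted p = 4.78e-58 and 1.27e-79). Opposite ways in the second went 12 of the windows that rose and 45 of those that fell in the first. Among bins, 28 rose and 122 fell in both, with 7.63 and 10.4 by chance (exact adjusted p = 6.90e-09 and 9.85e-94), and 145 and 159 went opposite ways. With met-2 against N2 paired with set-25;nrde-3 against nrde-3, which share no library, 147 windows rose and 197 fell in both, with 61.8 and 78.5 by chance (one-sided Fisher's exact adjusted p = 3.35e-26 and 2.17e-44). Of windows that rose and fell in the first, 49 and 164 went the opposite way in the second. Among bins, 224 rose and 187 fell in both, with 62.9 and 71.6 by chance (exact adjusted p = 1.01e-74 and 8.37e-44), and 72 and 99 went opposite ways. In the pair of met-2 against N2 and met-2;nrde-3 against nrde-3, which share no library, 78 windows rose and 196 fell in both, with 66.1 and 102 by chance (one-sided Fisher's exact adjusted p = 0.0713 and 1.39e-23). Opposite ways in the second went 109 of the windows that rose and 258 of those that fell in the first. Among bins, 70 rose and 300 fell in both, with 88.3 and 214 by chance (exact adjusted p = 1.00 and 9.88e-11), and 342 and 429 went opposite ways. Each adjusted p is over 48 overlap tests, and adjoining windows are not independent. The tests asked for a shared direction alone, and chance counts for opposite ways were not computed. Where opposite counts came near or above the shared ones, a small p cannot tell shared direction from the same features being called in both.

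The balance of higher and lower bins depended on the settings in several comparisons. Besides the splits with library totals, with windows, without the right end of chromosome I and without met-2;nrde-3 replicate 3, it turned in these cases, with the number of higher bins (or bins above 0) given first. For set-25 against N2 it was 395 and 643 with the stricter filter, 957 and 1021 with only the groups compared and 936 and 1064 with voom. For met-2;nrde-3 against N2 it was 8 and 7 with only the groups compared. There the balance also turned with both low-complexity libraries left out, a fit with replicate 3 alone in met-2;nrde-3. For met-2;nrde-3 against met-2 it was 4464 and 4664 with only the groups compared. For met-2;nrde-3 against nrde-3 it was 212 and 118 with only the groups compared and 373 and 364 with voom. For set-25;nrde-3 against nrde-3 it was 106 and 404 with the stricter filter and 412 and 487 with only the groups compared. For the set-25 interaction it was 50 and 52 with DESeq2, 14 and 27 with the stricter filter, 58 and 59 with only the groups compared and 66 and 79 with voom.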
